A study of Mus musculus with 8 samples.

How the data were processed

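PRDM16 binding to chromatin was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole cortex lysates of mouse embryos at E15.5. Per the labels, chromatin was crosslinked with paraformaldehyde and EGS, sheared by sonication and precipitated with a PRDM16 antibody. Each genotype had 2 ChIP libraries and 2 input libraries. The wild-type (WT) embryos carried floxed Prdm16 alleles without Cre, and the conditional knockout (cKO) embryos carried the same alleles with Cre expressed from the Emx1 locus, which is active in the dorsal telencephalic lineage. Peak lists of the 4 ChIP libraries were used. The input libraries, and the H3K27ac and H3K4me data that the series design mentions, were not analysed here.

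The submitters' processing notes name FastQC, cutadapt, Bowtie2 2.2.8, MACS2 2.1.1 and the mm10 build, without their settings. The authors deposited 1 narrowPeak list per ChIP library, so peaks were called per library and not on pooled replicates. In these deposited lists the enrichment of each peak is a fold over the local background, a ratio. The authors' peak significance is given in the deposited lists as −log10 of the p-value and −log10 of the q-value. The largest q-value kept was 0.0491 in WT replicate 1, 0.0440 in WT replicate 2, 0.0465 in cKO replicate 1 and 0.0454 in cKO replicate 2. All fold enrichments in the text are the authors' values. They describe and rank peaks, and were not used as a measure of change between genotypes. Which input served as the control of which ChIP library is not given in the sources used here.

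Peaks on chromosomes 1 to 19, X and Y were kept, and overlapping intervals within a list were merged. This left out 12 and 14 lines on unplaced contigs in WT replicates 1 and 2, and 37 and 19 in cKO replicates 1 and 2. A region counted as shared by 2 lists when at least 1 bp overlapped. A region of a genotype was the union of overlapping peaks from both of its replicates, and its fold enrichment is the mean ± SD of the strongest peak in each replicate (n = 2). Chance overlap was measured with 100 random circular shifts of a list along its chromosomes. Shares carry Wilson 95% intervals, which cover counting error only. Coordinates are in mm10 and count from 1.

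The lists hold no read totals. Depth was therefore read from the peaks themselves. MACS2 reports the fold as the summit pileup over the local background, each raised by 1, and its p-value follows from the Poisson distribution, so the whole-number pileup and the background can be solved for together. This returned a whole-number pileup within 0.0001 of the listed −log10 p-value for 99.88% to 99.96% of the summits tested per library; 5 and 32 highly significant peaks of WT replicates 1 and 2 were not tested. Whole-number pileups mean that the ChIP libraries had not been scaled. The smallest background of a library stands for its genome-wide pileup, which is the read number times the fragment length over the genome size. The shortest peaks, which MACS2 sets by the fragment length, were of 166, 179, 166 and 163 bp, so fragment length differed little between libraries. A detection limit was set per library as the smallest fold that passes its own p-value threshold at its median background, and a second limit as the 5th percentile of the folds it called.

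Gene positions came from a RefSeq table of the GRCm38.p6 assembly, which is the mm10 assembly, with 21883 protein-coding genes. The table gives no strand and no exons, and a genome sequence was not used here. The design fixed beforehand called for transcription start sites, exons, introns and sequence motifs. In their place, a region was assigned to the gene whose body holds its summit or whose nearer end lies within 100 kb, and "gene end" means a summit within 1 kb of either annotated end of a gene. Exons and introns were not separated, and motifs were not tested.

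The 19 gene lists, with 350 entries and 335 distinct symbols, were fixed, and all symbols were found in the table. They cover radial glia, intermediate progenitors, upper-layer neurons, deep-layer neurons, neuronal migration and guidance, the Notch, Wnt, and TGF-beta and BMP pathways, oxidative stress and mitochondria, brown fat, interneurons, Cajal-Retzius cells, choroid plexus and cortical hem, the astrocyte and oligodendrocyte lineage, endothelial and mural cells, microglia, ubiquitous genes, liver and skeletal muscle. For each list an exact conditional test, two-sided, compared the number of members with at least 1 region with all protein-coding genes, stratified into 10 groups by the length of genome nearest to each gene. Values were adjusted by the Benjamini-Hochberg method over the 19 lists, with a threshold of 0.05. Gene-end shares and shares of regions were compared with Fisher's exact test. Numbers of regions per library were compared with an exact permutation test over the 4 libraries.

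The genes named were chosen by rule. They are Prdm16 and Pdzrn3; the nearest genes of the 15 regions with the highest mean WT fold, 1 per gene, among those in both WT lists and neither cKO list that lie within 100 kb of a gene; in each list, up to 3 members with the highest fold; and the nearest genes of the 5 regions with the highest cKO fold among those in both WT lists and of the 5 among those in neither. Some genes that the rule takes are not reported here. The groups, main tests, gene lists, naming rule and most alternatives were chosen before the data were examined. Some tests were chosen later, among them those of the share of regions at list genes, of gene families and of X-linked genes. The alternatives were a −log10 q-value of at least 5, lists of equal length, a reciprocal overlap of 50%, autosomes only, unmerged intervals, other gene-end and distance limits, no stratification, and leaving out each replicate in turn.

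The list test was tested on simulated data over the 21883 genes: 4.8% of random lists of 20 genes gave p under 0.05, and 57.0% of lists drawn with a 3-fold weight on genes with a region did. In the same step the pileups of all 4528 simulated peaks were recovered, and 0 of 556 overlap calls differed from a brute-force count. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

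The labels do not say whether the replicates came from separate embryos, so the spread between replicates may be technical. In the deposited peak names both WT libraries share 1 library identifier and both cKO libraries another. The identifier was read here as a library pool or batch, which no label states; if that reading is right, a difference between pools and a difference between genotypes cannot be told apart. What WT libraries miss was read from each other: WT regions of 1 replicate in the same range of fold as each of 10 groups of cKO regions by fold were looked up in the other replicate, and again with regions matched by summit pileup over local background, since the fold raises both by 1 and so depends on depth. This comparison was chosen after the data were seen.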

Results

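PRDM16 is a zinc-finger transcription factor of the PR-domain family that is expressed in radial glia, the neural stem cells of the embryonic cortex. Its binding was mapped by ChIP-seq in the cortex at E15.5 in 2 WT and 2 cKO libraries. Per the labels, the cKO combined floxed Prdm16 alleles with Cre from the Emx1 locus, which is active in the dorsal telencephalic lineage. The comparison asks which sites PRDM16 occupies in the developing cortex, with the cKO as the control for the antibody. WT replicates 1 and 2 held 13852 and 26652 enriched regions, and cKO replicates 1 and 2 held 4553 and 3088. Peak lists do not measure Prdm16 expression, so the amount of the protein left in the cKO libraries was not checked here.

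Far fewer regions were called in the cKO cortex than in the WT cortex. The mean was 20252 ± 9051 regions in WT and 3820.5 ± 1036 in cKO (SD, n = 2 each), a ratio of 5.30, and both cKO libraries lay below both WT libraries. An exact two-sided permutation test gave p = 0.333, which is the smallest value that 2 libraries against 2 allow. WT regions were also wider, with median widths of 270 and 300 bp in the WT replicates and 217 and 212 bp in the cKO replicates. The highest fold enrichment in a list was 228 and 101 in WT replicates 1 and 2 and 34.4 and 30.4 in cKO replicates 1 and 2. The 228-fold peak of WT replicate 1 was not among the regions found in both WT lists. The highest mean fold of a region found in both lists of a genotype was 82.2 in WT and 31.2 in cKO. The genome background was 0.777 and 1.78 reads per base in the WT replicates and 2.95 and 2.52 in the cKO replicates, so the cKO libraries with fewer regions had the higher background pileup.

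**Figure D1:**
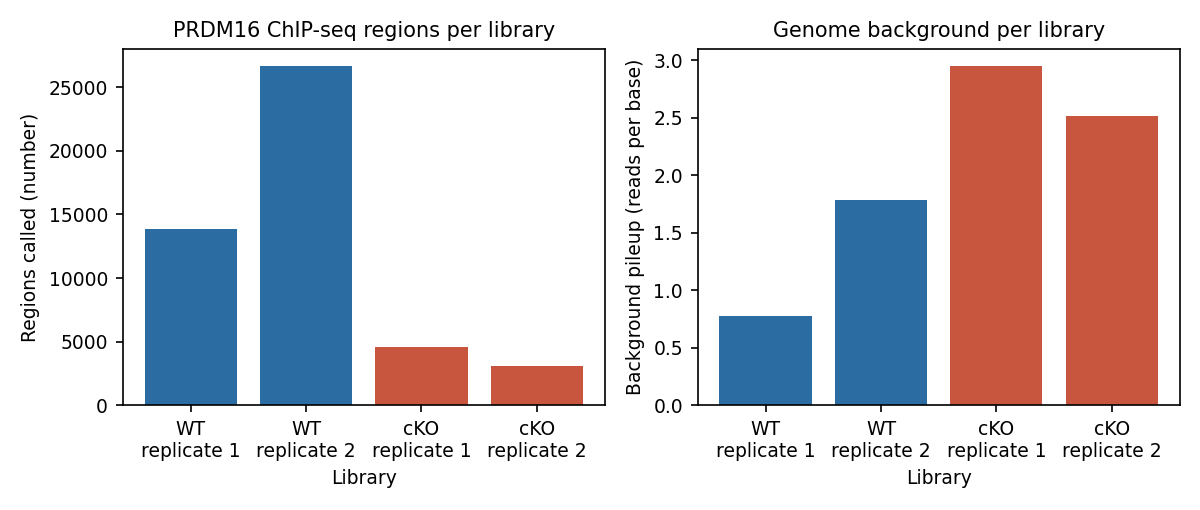
Bars show, for each of the 4 ChIP libraries, the number of regions called (left, number) and the genome background pileup recovered from the peak lists (right, reads per base). Both WT libraries hold more regions (13852 and 26652) than both cKO libraries (4553 and 3088), while the cKO backgrounds (2.95 and 2.52) are the higher ones.

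Replicates of a genotype shared many regions. Of the regions of WT replicate 1, 78.2% (95% interval 77.5 to 78.9) overlapped a region of WT replicate 2, against a mean of 0.759% after random shifts. The reverse share was 38.7% (38.2 to 39.3), replicate 2 being the longer list. In the cKO, 38.0% (36.6 to 39.5) of replicate 1 and 56.3% (54.6 to 58.1) of replicate 2 were found in the other replicate. Between genotypes the overlap was smaller in each list: 7.10% of the regions of WT replicate 1 were found in cKO replicate 1 and 5.74% in cKO replicate 2. In the other direction, from the shorter cKO lists, 21.5% of cKO replicate 1 were found in WT replicate 1 and 30.9% in WT replicate 2, and 25.8% and 35.5% of cKO replicate 2. With lists of equal length, the share of WT replicate 2 in replicate 1 was 66.6%.

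In the WT cortex, PRDM16-enriched regions were assigned to genes of radial glia, cortical neurons and their signalling pathways, and most were not called in the cKO. Both WT replicates shared 10090 regions, of which 9232 (91.5%, 90.9 to 92.0) overlapped no region in either cKO list. In 99.2% of the 9232, both WT folds were above both cKO detection limits. With the lower WT fold divided by 2, that held for 47.1% (4351 of 9232). A region not called in the cKO may thus keep a weaker signal there. The 9232 regions are called WT-only regions, and without WT replicate 1, which leaves the longer list alone, they numbered 24913. Their strongest assigned member lay at Fezf2, a transcription factor gene of deep-layer projection neurons, on chromosome 14 from 12337183 to 12338970, within 1 kb of a gene end, with a fold enrichment of 75.9 ± 12.3. Next came a region at the end of Ccny, which encodes a cyclin, with 54.7 and 83.0 in WT replicates 1 and 2, and regions in the bodies of Ralgapa2 (61.7 ± 4.89) and Myo1d (56.5 ± 2.24). Ahi1, a cilium gene, had a region 2174 bp beyond its end with 60.7 ± 4.07. In the body of Notch2, a Notch receptor gene, a region on chromosome 3 from 98042721 to 98044058 reached 51.5 ± 14.3.

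Other genes among the 15 with the highest regions within 100 kb of a gene included Erbb4, a neuregulin receptor gene, with a region in its body at 37.0 and 63.9 in the WT replicates, and Auts2, a gene linked to autism, at 49.5 ± 3.46. Acvr1b, an activin receptor gene, had 47.8 ± 9.11 in its body. Ttyh1, a radial glia gene, had 46.4 ± 23.9, and the acid-sensing channel gene Asic2 had 46.4 ± 2.44. The remaining names were Mthfd2l (55.0 ± 22.7), Ifna13 (53.7 ± 1.42), BC048507 (50.3 ± 11.7) and Slc36a4 (47.6 ± 2.00, 32526 bp outside the gene).

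Prdm16 itself carried 11 WT-only regions. The strongest lay on chromosome 4 from 154313044 to 154313839, 2788 bp outside the annotated gene, with 24.6 ± 1.36; 9 others lay in the gene body and 1 at a gene end. The cKO lists held 2 and 3 regions around Prdm16, with folds of 3.48 to 6.14, none of them overlapping a region of both WT lists. The cKO replicate 1 region from 154634592 to 154635015 did overlap a 4.64-fold region held by WT replicate 1 alone. Pdzrn3, which encodes a RING-finger ubiquitin ligase, carried 8 WT-only regions, the strongest in its body on chromosome 6 from 101307895 to 101308646 with 16.6 ± 6.43. Both cKO lists kept a region at an end of Pdzrn3, with 12.2-fold and 9.25-fold enrichment. Both WT lists held their strongest region around Pdzrn3 at this same site, with 24.8 and 30.7 in WT replicates 1 and 2. Around Sox2 the WT lists held 19 and 22 regions and the cKO lists 1 and 0. Around Fezf2 the counts were 8 and 9 against 0 and 0. The WT libraries share a library identifier that the cKO libraries do not, so these differences follow any batch that the identifier marks as well as genotype; no label says what it marks.

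**Figure D2:**
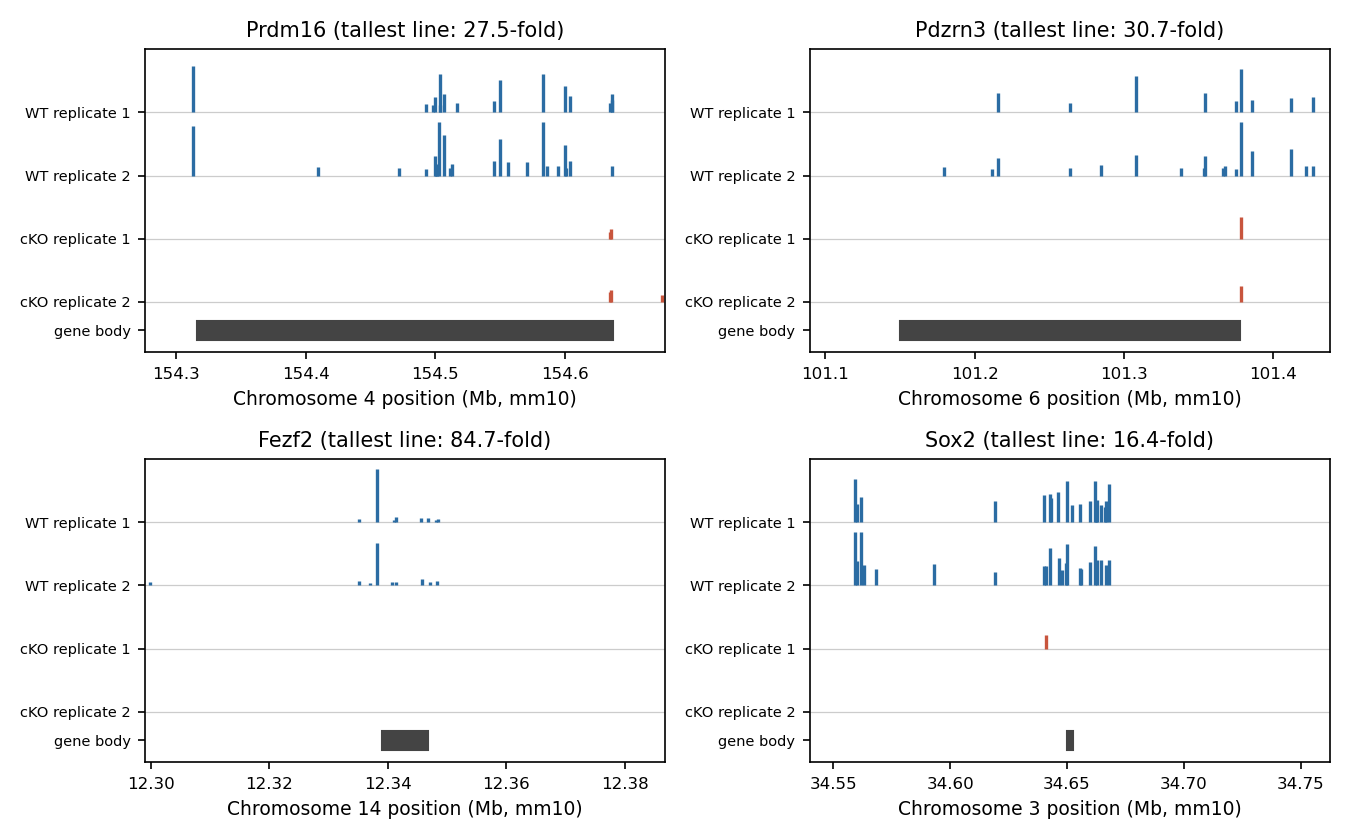
Peaks of each library at Prdm16, Pdzrn3, Fezf2 and Sox2 along the chromosome (Mb, mm10); each vertical line is a peak at its summit, its height the fold enrichment relative to the tallest peak of the panel, and the dark bar is the annotated gene body. WT lists hold 16 and 22 regions at Prdm16 and 19 and 22 at Sox2, and cKO lists 2 and 3 at Prdm16 and 1 and 0 at Sox2.

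WT-only regions were assigned to genes of radial glia, and of the neurons and progenitors they give rise to, more often than gene spacing predicts. The test takes no account of open chromatin or expression. It therefore cannot separate PRDM16 targets from genes that are active in the cortex. All 27 radial glia genes had at least 1 WT-only region, against 8.20 expected from the length of genome nearest to them (exact conditional test, adjusted exact p = 4.2e-18). The highest were Notch2, Ttyh1 and Slc1a3, the glutamate transporter gene of radial glia, at 43.4 ± 6.73. Among intermediate progenitor genes 11 of 16 had one, against 2.07 (adjusted exact p = 1.1e-07), led by the proneural gene Neurog2 at 27.4 ± 5.09, Gadd45g at 18.3 ± 11.4 and the antiproliferative gene Btg2 at 10.2 ± 3.72. Upper-layer neuron genes had 13 of 15 against 7.14 (adjusted exact p = 0.0045), with Pou3f3 at 18.1 ± 7.62, Lmo4 at 16.7 ± 5.66 and Mef2c at 11.3 ± 2.95. The regions named for Neurog2, Btg2, Gadd45g and Mef2c lay 10747, 13783, 54284 and 65217 bp outside the gene. Deep-layer neuron genes had 10 of 14 against 5.98 (adjusted exact p = 0.042), with Fezf2, Lmo3 at 33.6 ± 23.3 and Sox5 at 21.2 ± 5.50. Genes of neuronal migration and guidance had 20 of 27 against 11.2 (adjusted exact p = 0.00068), with the Slit receptor gene Robo1 at 40.6 ± 3.90, the ephrin receptor gene Epha4 at 18.4 ± 0.698 and the chemokine receptor gene Cxcr4 at 17.3 ± 5.59.

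Signalling pathway genes followed. The Notch pathway had 12 of 21 genes with a region against 4.76 expected (adjusted exact p = 0.00077), with Notch2, Notch1 at 26.8 ± 0.794 and Maml3 at 14.5 ± 2.99. Of the 12, Notch1, Notch2, Hes1 and Hes5 are also in the radial glia list, and Dll1 and Mfng in the intermediate progenitor list. The Wnt pathway had 15 of 24 against 7.20 (adjusted exact p = 0.0021), with Tcf7l1 at 29.2 ± 9.17, the secreted Wnt inhibitor gene Sfrp1 at 18.6 ± 4.80 and the receptor gene Fzd9 at 18.0 ± 0.307. Genes of the TGF-beta and BMP pathway had 13 of 26 against 8.27, which did not pass (adjusted exact p = 0.073). Their highest members were Id4 (16.2 ± 3.80), Bmpr1b (13.1 ± 7.61) and Id2 (12.9 ± 4.03). The Id4 and Id2 regions lay 89365 and 28595 bp outside the gene.

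Genes of other cell types were mixed. Of the regions named below, those of Prdx6, Prox1, Psmb2, Otx2 and Kl lay 15122, 19747, 29125, 42391 and 57944 bp outside the gene. The astrocyte and oligodendrocyte lineage had 10 of 18 against 4.01 (adjusted exact p = 0.0025), with Nfib at 26.1 ± 4.89, Nfia at 20.8 ± 3.63 and Sox8 at 12.9 ± 2.13. Interneuron genes had 10 of 20 against 5.43 (adjusted exact p = 0.049), with Erbb4 and with Prox1 at 14.8 ± 2.45. Choroid plexus and cortical hem genes had 8 of 16 against 4.17 (adjusted exact p = 0.049), with Kl at 14.7 ± 4.15, Wnt8b at 13.2 ± 4.76 and Otx2 at 13.0 ± 7.17. The test was not passed by Cajal-Retzius genes (5 of 10 against 3.09, adjusted exact p = 0.37), brown fat genes (4 of 15 against 3.82, adjusted exact p = 1.0), genes of oxidative stress and mitochondria (2 of 19 against 3.41, adjusted exact p = 0.64), endothelial and mural genes (2 of 17 against 4.76, adjusted exact p = 0.20) or microglia genes (1 of 15 against 1.71, adjusted exact p = 1.0). Nor was it passed by ubiquitous genes (4 of 20 against 1.74, adjusted exact p = 0.11), liver genes (2 of 19 against 1.65, adjusted exact p = 0.80) or skeletal muscle genes (1 of 11 against 1.05, adjusted exact p = 1.0). Among lists that did not pass, members with a WT-only region included the antioxidant enzyme genes Gpx4 (9.12 ± 6.93) and Prdx6 (6.92 ± 2.84), the early B-cell factor genes Ebf2 (10.4 ± 0.0400) and Ebf3 (10.3 ± 4.16), the deiodinase gene Dio2 in its body, the endothelial adhesion gene Pecam1 (12.7 ± 3.41), the proteasome gene Psmb2 (10.7 ± 4.82) and the muscle precursor gene Pax7 (19.4 ± 1.10).

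**Figure D3:**
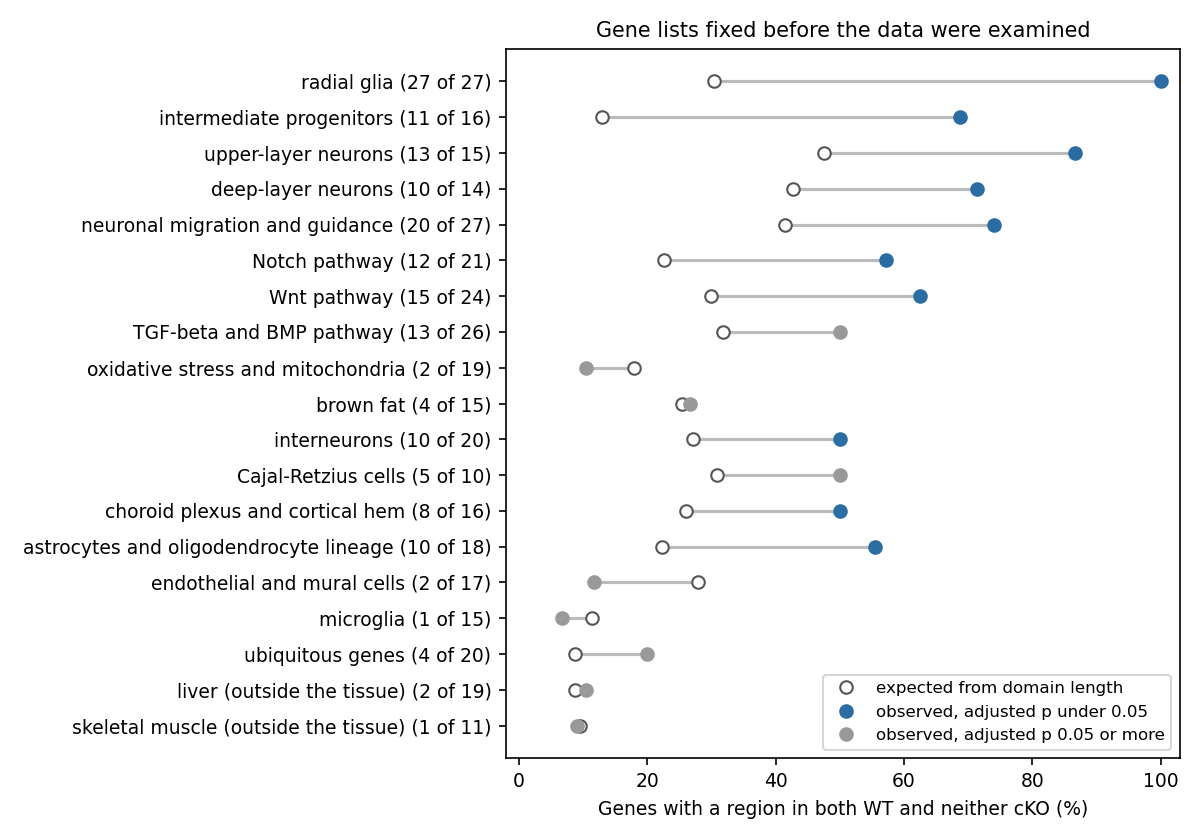
For each of the 19 gene lists, the share of genes (%) with a region in both WT lists and neither cKO list (filled circle, blue where the adjusted p was under 0.05 and grey otherwise) and the share expected from the length of genome nearest to the genes (open circle). By the difference between the shares, radial glia lie farthest from expectation, with 27 of 27 genes against 8.20.

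In all, 10 of the 19 lists passed, each above expectation, and 3589 of the 21883 protein-coding genes (16.4%) had a WT-only region. Among the 858 regions of both WT lists that were also in a cKO list, 3 of the lists passed by the same exact conditional test: intermediate progenitors (5 of 16 genes against 0.414, adjusted exact p = 0.00056), migration and guidance (8 of 27 against 1.80, adjusted exact p = 0.0021) and the astrocyte and oligodendrocyte lineage (4 of 18 against 0.719, adjusted exact p = 0.029). Among regions found in both cKO lists 0 of 19 passed, and 4 had an unadjusted p under 0.05, all above expectation. The 4 were the astrocyte and oligodendrocyte lineage, upper-layer neurons, brown fat and radial glia. Radial glia had 6 of 27 genes against 2.44 (exact conditional unadjusted p = 0.029). Such regions reached 1476 genes, against 3589 for WT-only regions, so the tests differ in power. Among those in both cKO lists and neither WT list 0 passed, and 3 had an unadjusted p under 0.05. The difference between the region classes was tested as a share of regions. This test was not in the design fixed beforehand and was chosen after the data were seen, though its prediction was written before its result. Radial glia genes took 97 of 9232 WT-only regions (1.05%) and 7 of 1723 cKO regions (0.406%). The odds ratio was 2.60 (1.21 to 6.66, Fisher's exact two-sided p = 0.0095, adjusted exact p = 0.090). Regions are not independent, as several can lie at 1 gene (15 of the 97 at Sox2), so the interval may be too narrow. The classes also differ in their gene-end share, which was not matched. For migration and guidance the odds ratio was 3.38 (1.39 to 10.7; exact p = 0.0027, adjusted exact p = 0.051). By this Fisher's exact test 0 of 19 lists passed, and 4 had an unadjusted p under 0.05, the other two with odds ratios below 1 (oxidative stress and mitochondria 0.124, exact p = 0.030; brown fat 0.298, exact p = 0.041), so a difference between the classes was not shown for any list. With lists of equal length 2 of the 19 lists passed, radial glia and the Notch pathway, which share some members. The deep-layer call ended without WT replicate 1 or without cKO replicate 1 (adjusted exact p = 0.075 and 0.050), the upper-layer call without WT replicate 1 (0.053) and the choroid plexus call without WT replicate 2 (0.061; exact conditional test throughout). Ubiquitous genes passed without WT replicate 1 or cKO replicate 1 (exact adjusted p = 0.012 and 0.043), Cajal-Retzius genes without WT replicate 1, and TGF-beta and BMP genes without any 1 of the 4 libraries.

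WT-only regions lay mostly away from gene ends. Their summits fell within 1 kb of a gene end in 5.61% (5.16 to 6.10), elsewhere in a gene body in 46.3% and between genes in 48.0%, and 20.6% lay over 100 kb from any protein-coding gene. Randomly shifted positions fell at gene ends in 3.01%. Among the 858 regions of both WT lists that were also in a cKO list, 22.4% (19.7 to 25.3) were at gene ends, an odds ratio of 4.85 against WT-only regions (Fisher's exact two-sided p = 5.1e-53). Regions in both cKO lists were at gene ends in 37.9% (35.6 to 40.2), and those in both cKO lists and neither WT list in 44.2% (40.8 to 47.7), odds ratios of 10.3 and 13.3 against WT-only regions (exact p = 1.3e-256 and 1.1e-183). Regions are not independent replicates, so these p-values describe the lists and not a spread between embryos.

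**Figure D4:**
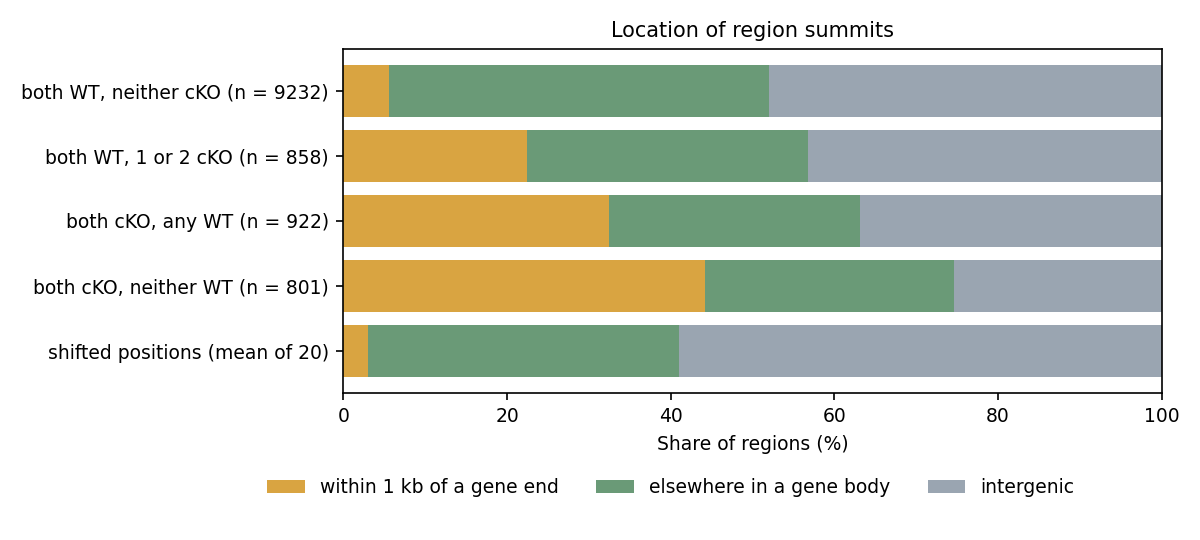
Share of region summits (%) within 1 kb of an annotated gene end, elsewhere in a gene body or between genes, for 4 classes of regions and for the mean of 20 random shifts. The gene-end share goes from 5.61% in WT-only regions to 44.2% in regions of both cKO lists and neither WT list.

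Some regions remained in the cKO cortex. Both cKO lists shared 1723 regions, of which 922 (53.5%, 51.2 to 55.9) overlapped a WT region and 801 (46.5%) did not. A single cKO list in place of both gave more: 3088 regions without cKO replicate 1, of which 1786 were in neither WT list, and 4553 without cKO replicate 2, of which 2860 were in neither. The strongest cKO regions also found in both WT lists lay near Rfx7, an RFX transcription factor gene (31.2 ± 1.09), at the end of Nipsnap2 (28.0 ± 9.08), near Gtf3c5, a subunit gene of an RNA polymerase III factor (27.6 ± 4.41), in Niban2 (28.2 and 21.7 in the cKO replicates) and at the end of Vps36, an endosomal sorting gene (24.9 ± 4.86). The strongest found in neither WT list lay near the alpha-actinin gene Actn1 (17.4 ± 3.64), in Antxr2 (16.1 ± 5.19), near Glrx3 (14.6 ± 3.93), at the end of Hsd3b7 (13.8 ± 3.99) and near Asb10 (13.7 ± 0.218). Without WT replicate 2 the overlap with WT fell to 34.6%, and with lists of equal length to 10.4%.

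The share of WT regions that were also called in the cKO did not rise with WT fold enrichment. Of the 1009 shared WT regions with the lowest mean fold, 13.2% (11.2 to 15.4) were in a cKO list, and of the 1009 with the highest, 8.72% (7.13 to 10.6), a ratio of 0.662 (0.513 to 0.854) in a comparison chosen after the data were seen.

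**Figure D5:**
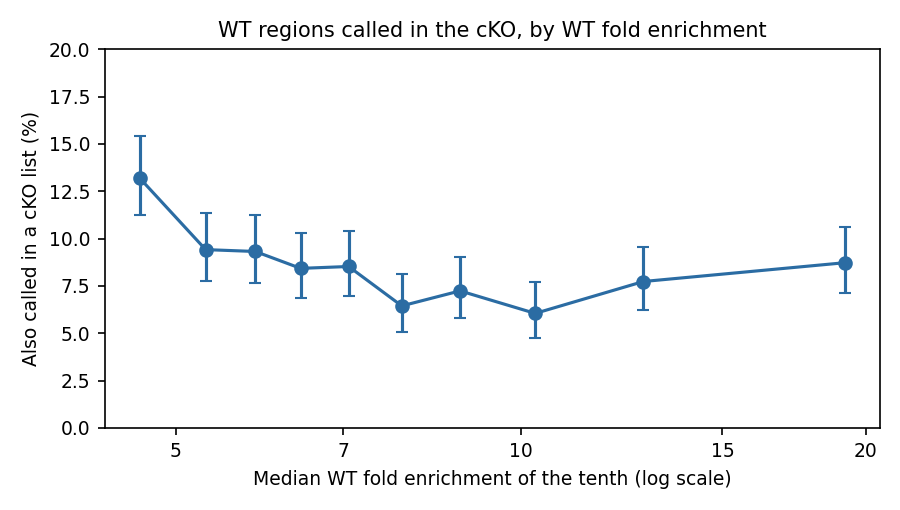
Share (%) of regions of both WT lists that were also called in a cKO list, in 10 groups of 1009 regions by mean WT fold enrichment (log scale); bars are Wilson 95% intervals. The share is 13.2% in the lowest group and 8.72% in the highest.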

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

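The tests on draws to equal numbers of regions and with a replicate block were chosen only after the results were seen. With the replicate number as a block, WT held 3.04 and 8.63 times as many regions as cKO, and the exact two-sided permutation p was 0.5, the smallest that 2 pairs allow. For the overlaps, regions and gene lists, no paired analysis was made, as they join both replicates of a genotype and come from no test over samples. Motif tests, and their alternatives, were not run, as a genome sequence was not used here. Among values recomputed for the comparisons, 68 kept their call, or stayed within their interval or within 1.5 times, and 36 moved. The ratio of WT to cKO regions ranged from 3.63 to 6.98 and the gene-end odds ratio from 4.31 to 7.54, always above 1. With a −log10 q-value of at least 5 the cKO mean was 2447.5 regions, the overlaps of WT replicate 1 and of cKO replicates 1 and 2 with their partners were 79.9%, 40.5% and 60.2%, 93.8% of shared WT regions were in neither cKO list, and 49.2% of shared cKO regions were in a WT list. With lists of equal length the 4 overlaps were 67.5%, 66.6%, 47.4% and 47.7%, 1896 of 2052 WT regions (92.4%) were in neither cKO list, 10.4% of cKO regions were in a WT list and 1307 were in neither, and 2 gene lists passed; shorter lists hold fewer regions by construction. With a 50% reciprocal overlap the overlaps were 48.9%, 25.4%, 34.0% and 50.1%, and the 2 shares 94.6% and 43.8%. Regions at gene ends alone left 4 lists, and the interneuron list then had 0 genes with a region, a ratio of 0 to expectation in place of 1.84; few regions lie at gene ends. Leaving out each replicate in turn gave 13852 to 26652 WT regions, 12662 was the count in neither cKO list without WT replicate 2, and the full range of that count was 9378 to 24913 (91.4% to 94.0%). It gave 3088 to 4553 cKO regions without a cKO replicate. Over all 4 omissions 34.6% (without WT replicate 2) to 45.2% (without WT replicate 1) of cKO regions were in a WT list, and 944 (without WT replicate 1) to 2860 (without cKO replicate 2) were in neither; a single list stands in for 2 there, and the highest WT count is that without WT replicate 1. Radial glia passed under all 11 alternatives run on the lists (highest adjusted p 0.0032), and Notch, Wnt and intermediate progenitor genes under 10. The call was lost under 7 alternatives for choroid plexus and hem, 5 for deep layers, 5 for interneurons, 4 for upper layers, 3 for the astrocyte and oligodendrocyte lineage and 2 for migration, and the cause was not tested. TGF-beta and BMP genes passed under 8 (lowest adjusted p 0.00018). Drawn to 1723 regions, WT-only regions reached a median of 12 radial glia genes (8 to 18 in 100 draws), against 6 for the cKO regions. Numbers of regions at named genes stayed within 1.5 times in 405 recomputed values and moved in 205. They depended most on the WT lists and the rule for regions. Of 61 genes, 16 stayed without WT replicate 1, 50 without WT replicate 2, and 60 and 61 without cKO replicates 1 and 2. With lists of equal length 12 stayed and 16 had no region, and with regions at gene ends alone 2 stayed and 52 had none. Of the 4 libraries depth limits WT replicate 1 most: it had a background of 0.777 reads per base and its smallest callable fold at the median background was 3.53, against 3.01 in WT replicate 2 and 3.18 and 3.26 in the cKO replicates.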

Other observations

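The tests of lower read depth of the cKO libraries, of a weaker precipitation and of library batches, the second detection limit, the regions that WT libraries miss of each other, the gene families, the X-linked genes and the distant regions were chosen only after the results were seen. The test of the share of regions at radial glia genes was also chosen after the data were seen, though its prediction was written before its result.

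Some genes carried many WT-only regions. Auts2 had 31, Bach2, a transcription repressor gene, 24 and Msi2, an RNA-binding protein gene of neural progenitors, 22. Their domains, the lengths of genome nearest to them, were 1271, 455 and 457 kb. Auts2 also had 6 regions of both cKO lists, Bach2 0 and Msi2 1. In all, 45 genes had at least 10 WT-only regions. Sox2, the stem cell transcription factor gene, had 15 within a domain of 203 kb, while Sox5 had 15 within 1154 kb. Of the Sox family, 12 of 19 genes had a WT-only region against 5.95 expected (exact conditional test, adjusted p = 0.0075 over 21 families). Olfactory receptor genes had 3 of 1110 against 62.4 (exact adjusted p = 6.1e-24) and vomeronasal receptor genes 2 of 355 against 46.0 (adjusted p = 1.3e-18), both below expectation. None of the 39 Hox genes had one, against 1.80 expected (exact adjusted p = 0.34).

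The strongest WT-only region of all lay far from any protein-coding gene, on chromosome 12 from 50119798 to 50123401, with a fold enrichment of 82.2 ± 26.6 (SD, n = 2). It is 220 kb from Prkd1. A further region on the other side of Prkd1, from 51001581 to 51002898, had 50.4 ± 7.5. X-linked genes had few regions in both genotypes: 71 of 966 had a WT-only region against 222 expected from the length of genome nearest to them (exact conditional p = 5.0e-48), and 9 had a region of both cKO lists against 76.6 (p = 1.6e-24).

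The cKO lists held fewer regions than the WT lists. Lower depth of the cKO libraries is argued against by their background pileup, which was 2.14 times that of the WT libraries. A precipitation weakened alike at all sites would spare the strongest sites, but the share still called in the cKO was 0.662 times as high (0.513 to 0.854) in the highest group by WT fold as in the lowest; a precipitation that failed at all sites is not excluded by this. Loss of PRDM16 in the Emx1 lineage is a candidate explanation, and regions at radial glia genes were more frequent among WT-only regions than among cKO regions (odds ratio 2.60), although not past the threshold after adjustment (Fisher's exact adjusted p = 0.090). A difference between library batches cannot be told apart from it, since 0 library identifiers, read here as batches, hold both genotypes.

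A second pattern is the 801 regions found in both cKO lists and neither WT list. The detection limits themselves decide nothing here: 0.499% of these regions lay below both WT limits (4.37% with the second limit), but so did only 0.464% of all regions of both cKO lists (3.31%), and 46.0% of those above the limits were in neither WT list (45.1%), but WT libraries miss regions of each other above the limits too. A region in neither list must be missed by WT replicate 2. Misses by replicate 2 of equally enriched replicate 1 regions would give 26.4% of all cKO regions matched by fold (upper bound 29.1%). Matched by summit pileup over background they would give 27.2% (32.7%). The shares seen were 46.5% (44.1 to 48.8) and 46.6% (44.2 to 48.9). Both shares lay above these upper bounds. That argues against WT misses as the whole cause if WT replicate 2 misses cKO regions as often as equally enriched replicate 1 regions. Whether it does was not tested. The comparison looked up regions of the shallowest library (background 0.777) in a deeper one (1.78). The cKO libraries, with 2.95 and 2.52, were deeper than both WT libraries. How this difference in depth shifts the expected share was not tested. The comparison also takes such sites to be equally enriched in WT cortex. WT cortex also holds the cells outside the Emx1 lineage, so PRDM16 left there accounts for such regions only where WT libraries missed them. A higher detection limit of the WT libraries and PRDM16 left outside the Emx1 lineage both stay open as a partial cause. As the whole cause, each would need WT replicate 2 to miss cKO regions at a higher rate than those used here. The share fell with cKO fold, from 55.2% in the lowest group to 20.2% in the highest. Replicate 1, the shallower WT library, missed 85.0% to 5.49% of equally enriched replicate 2 regions. Signal at gene ends used by every cell stays open because its test had no power, with 0.525 of 20 ubiquitous genes expected to carry such a region and 0 found (ratio 0), and so does a batch, as 0 library identifiers hold both genotypes.

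WT replicate 2 held 1.92 times as many regions as WT replicate 1, with 2.29 times its background pileup. Greater depth of replicate 2 is a candidate explanation that stays open: of its regions absent from replicate 1, 32.5% had a fold less than 25% above the smallest that replicate 1 could call, and 64.0% with the second limit. The first limit is strict, since 6.93% of the regions of replicate 1 itself lie under the same bound. No biological explanation was tested, as both libraries belong to the same group.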
